A study of Homo sapiens with 36 samples.

How the data were processed

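RNA was measured in 36 libraries, 2 from each of 18 human cell types, all prepared with one extraction protocol as single-end QuantSeq 3' mRNA-seq FWD libraries, per the labels' protocols. This kit primes on the poly(A) tail and reads the 3' end of each transcript, so a transcript gives about 1 tag whatever its length. The groups were 11 epithelial cultures (airway, bladder, colon, esophageal, mammary, ovarian, pancreas, prostate, renal proximal tubule, thyroid and uterine endometrial cells), calcium-differentiated keratinocytes, melanocytes, astrocytes, the B-lymphoblastoid line GM12878 and the melanoma lines COLO 829, SK-MEL-5 and WM-266-4. The labels call the 2 libraries of a group biological replicates without saying whether they came from separate donors or cultures. The p-values therefore measure the spread between these libraries, which may be partly technical.

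The deposited gene tables have the column names of RSEM output and hold, per the file headers, an expected count, a TPM and an FPKM value for each Ensembl gene. The submitters' processing notes name the genome build hg19, STAR 2.5.4b, RSEM 1.3.0 and limma, with no role or order, and the annotation release is not given in the sources used here. The expected counts deposited by the authors are estimated reads per gene, not normalised, and can be fractional where reads map to several genes. The TPM values deposited by the authors are divided by effective transcript length and scaled to a fixed sum per library. The FPKM values deposited by the authors are scaled by the same lengths and by depth, and were not used here. Division by length does not suit tags counted at the 3' end, so expected counts, rounded to whole numbers, carried every main test, and TPM served as an alternative. A table of the whole series repeated the TPM of part of the genes by symbol and was not used here.

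The tables list 63677 Ensembl genes, of which 52181 matched a symbol in the gene name table used here. Genes with a symbol held 89.5% to 95.8% of the counts of a library. Y-linked genes, XIST and TSIX (540 identifiers) were left out of every step. Of the 544 symbols in the gene lists 541 matched a measured identifier. Genes with a second identifier on an alternate assembly share their reads with it. Expected counts split reads between near-identical genes, so values of paralogs such as the MAGEA, SPRR2, metallothionein (MT1) and KRT6 families are uncertain, as are those of readthrough transcripts. No genomic coordinates were used.

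The total expected count ranged from 2.62 M (Prostate replicate 2) to 53.7 M (Esophageal replicate 2), with a median of 19.4 M. A count of 0 allows a level of up to 3 counts of the total, which was 1.14 CPM in Prostate replicate 2 and 0.0559 CPM in Esophageal replicate 2. Such limits and intervals cover counting error only, since the reads carry no molecular identifiers. CPM here means rounded expected counts per 1 M of a library's total. Values given as mean ± SD cover the 2 libraries of a group unless another n is stated.

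Tests used edgeR 4.0.16 in R 4.3.3 with TMM normalisation, the filterByExpr filter on low counts, and the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. All adjusted p-values without another tool's name come from this test. Log2 fold changes are fitted with edgeR's default prior count and are given with the standard error of the fit. Each of the 15 cell types other than the melanoma lines was compared with the mean of the other 14 in one fit of 30 libraries and 19408 genes. A gene was counted as restricted to a type when its adjusted p passed and its fitted log2 CPM lay at least 1 above that of every other type. The melanoma lines and melanocytes were fitted together (8 libraries, 18986 genes). For supplier and medium, the 2 libraries of each of 11 epithelial types were summed, and the 6 types from CellBiologics, grown in one medium per the growth protocols, were compared with the 5 from other suppliers (16228 genes). Similarity of libraries was the Pearson correlation across 20648 genes of log2 CPM with a prior count of 2. Genes are not independent replicates, so no p is given for it.

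Gene lists were written before the data were examined, together with the tests, the alternatives and the rule for named genes. There were 15 identity lists, 1 for each cell type, 14 lists for the melanoma comparison, 7 lists of other cell types and a list of HOX genes. They were tested with camera of limma on log2 CPM with a preset correlation of 0.01, adjusted over the lists of a family, and again with the correlation estimated from the data. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

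Named genes followed a fixed rule. For each cell type these were the 4 restricted genes with the largest margin over the next type and at least 10 CPM in both libraries. For each list they were up to 6 members with the largest fold per comparison, passed or not, with TP63, GRHL2, EPCAM, PAX8, WT1, SOX10 and MITF in every type. In melanoma they were the 12 higher and 12 lower genes called in all 3 lines with the largest smallest fold, and 4 genes per line called higher than in both other lines. Between suppliers they were the 10 genes with the largest fold in each direction. Genes that are commonly polymorphic, immunoglobulin and T-cell receptor segments, mitochondrial genes, pseudogenes, antisense RNAs and unnamed loci were never named. HLA genes were also left unnamed, a choice made after the values were seen, and some genes that met the rule were not used here.

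Each gene test was run again with DESeq2 1.42.0 size factors, without the filter, with the DESeq2 Wald test, and with limma on log2(TPM + 1) and log2(TPM + 0.1). The restricted-gene and melanoma tests were also run with the replicate number as a block, with all 36 libraries in one fit, and with each library left out in turn. The supplier test was run without each cell type in turn and without replicate 1 or 2 of every type. Where a group was left with 1 library, that library was assumed to vary like the other groups. The 3 gene tests and the melanoma list test were tried on simulated counts drawn from the real means and library sizes. The restricted-gene step recovered 1.5% of genes raised 2-fold, 68.7% of those raised 4-fold and 100% of those raised 8-fold. The melanoma step recovered 6%, 59.7% and 93.9% at these folds, and the supplier step 0%, 53.7% and 97%. At most 0.042% of unchanged genes were called by edgeR, and camera called the raised list and none of the random ones. Genes were drawn independently and with one spread for all groups. These rates therefore do not cover lists whose genes move together, or a pair of unlike replicates.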

Results

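Gene expression was measured in 36 libraries of human cells, 2 from each of 18 groups, to compare the genes that different cell types use. The groups were 11 epithelial cultures, keratinocytes differentiated for 6 days in 1.2 mM calcium, melanocytes, astrocytes, GM12878 (a B-lymphoblastoid line) and COLO 829, SK-MEL-5 and WM-266-4, which are melanoma lines. The epithelial cultures were Airway, Bladder, Colon, Esophageal, HMEC (mammary epithelial cells), Ovarian, Pancreas, Prostate, Renal (proximal tubule), Thyroid and Uterine (endometrial). The total expected count was 2.62 M in Prostate replicate 2 and between 12.6 and 53.7 M in the other 35 libraries, with a median of 19.4 M over all 36. The melanoma line libraries, at 36.1 to 49.8 M, were deeper than all but 2 of the others, which were Esophageal replicate 2 and GM12878 replicate 2. A count of 0 therefore allowed up to 1.14 CPM in Prostate replicate 2 but only 0.0602 to 0.083 CPM in the COLO 829 libraries.

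The first question was whether libraries resembled their own replicate more than other cell types. For 33 of 36 libraries the nearest library, by Pearson correlation across 20648 genes, was the other replicate of its group. The exceptions were Ovarian replicate 1, nearest to Esophageal replicate 2 (r = 0.981), Pancreas replicate 1, nearest to Bladder replicate 2 (r = 0.935), and Pancreas replicate 2, nearest to Colon replicate 1 (r = 0.984). The replicates of Pancreas correlated at r = 0.888 and those of Prostate at r = 0.911, with 16.9% and 18.5% of genes differing 4-fold between the libraries. Melanocytes followed at r = 0.922 (12.1% of genes), HMEC at 0.945 and Astrocytes at 0.948, and the other 13 pairs lay at 0.967 or above.

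Colon, Renal and Thyroid cells formed the tightest group of different tissues, with a mean r of 0.977 between types and none below 0.972. Esophageal and Ovarian cells correlated at 0.972 with each other and at a mean of 0.955 with Colon, Renal and Thyroid. Pancreas replicate 2 correlated with these 3 types at a mean of 0.981 and Pancreas replicate 1 at 0.882. All 6 of these cultures came from one supplier (CellBiologics) and were grown in one medium. By comparison, Colon, Renal and Thyroid correlated at a mean of 0.874 with the 5 epithelial types of other suppliers, whose own pairs ranged from 0.833 to 0.946 (Bladder with Uterine). The melanoma lines correlated at 0.881 to 0.907 among themselves and at 0.830 to 0.839 with melanocytes. Melanocytes lay closer to Astrocytes (0.885) and to the epithelial cultures other than Prostate (0.848 with Thyroid to 0.878 with Esophageal). They were further from Prostate (0.780), Keratinocytes (0.784) and GM12878 (0.798). These means cover 2 unlike melanocyte libraries, as SK-MEL-5 correlated at 0.8079 and 0.8035 with replicate 1 and at 0.8557 and 0.8546 with replicate 2. The lowest mean between groups was 0.679, for Prostate with SK-MEL-5. The HOX genes, whose expression marks body position, did not separate Colon, Renal and Thyroid. No HOX gene at 5 CPM or more differed 4-fold between any pair of the 3 types, while 4 to 13 (of 8 to 18) did in pairs of the 5 types from other suppliers. Pairs of Colon, Esophageal, Ovarian, Renal and Thyroid differed in at most 1 (of 7 to 9 genes at that level), so the likeness was not particular to the first 3, but Pancreas, from the same supplier, differed from each of these 5 types in 4 (of 11 to 13) in the mean of its 2 unlike libraries. These counts are descriptions without a test.

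**Figure D1:**
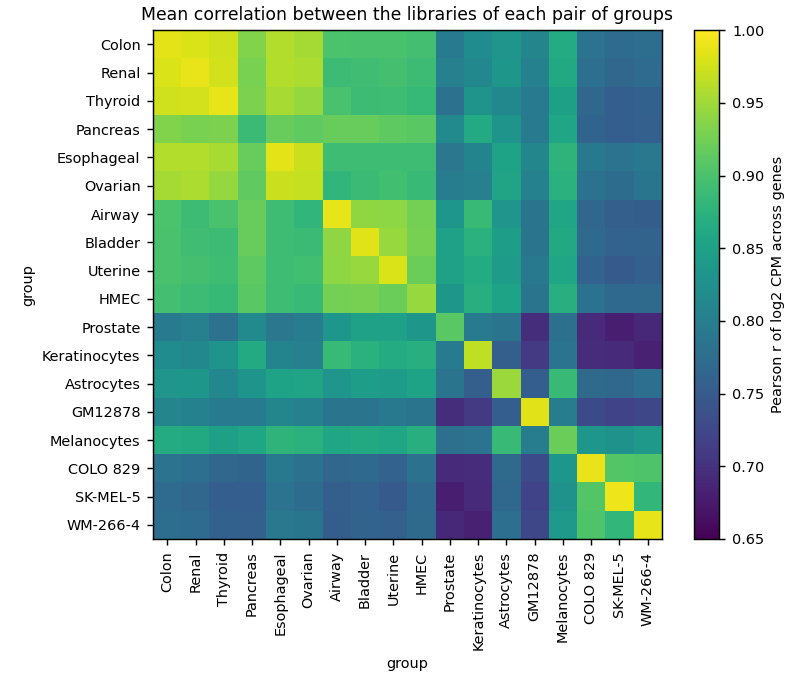
Mean Pearson correlation of log2 CPM across 20648 genes between each pair of the 18 groups, with the correlation between the 2 replicates of a group on the diagonal. Colon, Renal and Thyroid correlated with each other at a mean of 0.977, and Prostate with SK-MEL-5 at 0.679, the lowest value.

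The next comparison asked which genes were restricted to 1 of the 15 cell types other than the melanoma lines. The largest sets belonged to Prostate (1432 genes), GM12878 (1150), Keratinocytes (998), Astrocytes (727) and Melanocytes (354). Uterine had 127, HMEC 92, Bladder 89, Airway 55, Ovarian 54, Esophageal 33, Pancreas 29, Thyroid 22, Renal 8 and Colon 6. With a margin of at least 3 on the log2 scale the order changed, to 556 genes in GM12878, 265 in Keratinocytes, 241 in Astrocytes, 90 in Melanocytes and 69 in Prostate. Of the Prostate genes, 821 (57.3%) were at 1 CPM or more in every other type, against 31.1% of the Keratinocytes genes and at most 13.0% of those of any other type. The median effective length of genes was 1823 and 1842 nt in the Prostate libraries and 2006 to 2175 nt in the other 34, and Prostate replicate 1 had the highest mitochondrial share (7.74%).

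**Figure D2:**
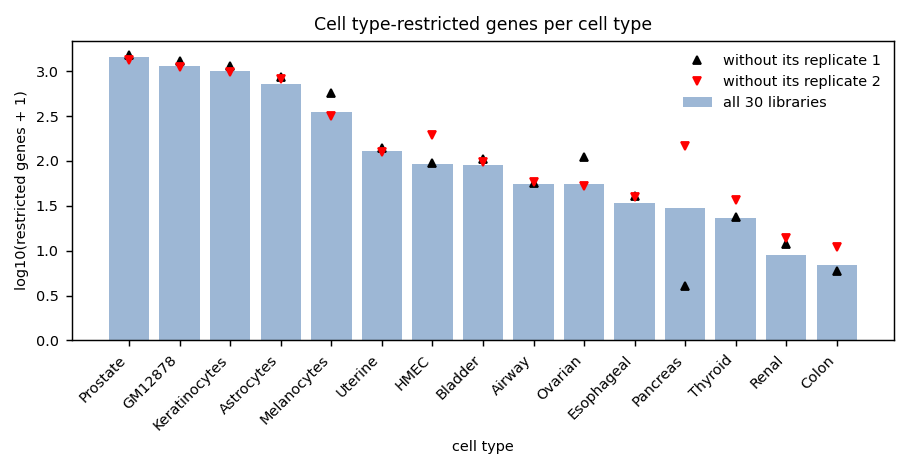
Number of genes restricted to each of the 15 cell types (adjusted p and a margin of 1 log2 unit over every other type), on a log axis, with the counts obtained when either replicate of the type was left out. Prostate, GM12878 and Keratinocytes had the largest sets, and Colon (6) and Renal (8) the smallest.

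Genes restricted to GM12878 included several of lymphocytes. TLR7, a receptor for single-stranded RNA, was at 226 CPM against 0.561 in Bladder, the next type, and CD52, a lymphocyte surface protein, at 75.1 against 0.253. The chemokine receptor CCR9 was at 23.7 CPM, with 2 counts in the next type. In Keratinocytes, LCE1A of the cornified envelope was at 237 and 572 CPM against 1.13 in Airway (adjusted p = 1.8e-14) and SPRR2B at 56.0 against 0.170. The defensin genes DEFB103A and DEFB103B, which are identical copies that share their reads, were each listed at 1028 CPM. Astrocytes carried POU3F3, a transcription factor of the developing brain (90.5 ± 54.1 CPM against 0.262 in Melanocytes), its neighbour PANTR1 (168 against 0.428) and DLK1 (269 against 0.728), with adjusted p-values of 1.1e-12 or less, and POU3F4 at 11.2 CPM, whose call was lost in the DESeq2 Wald test (adjusted p = 0.185). Melanocytes carried TYR, the first enzyme of melanin synthesis, at 17.5 CPM in replicate 1 and 542 in replicate 2 (log2 fold over the mean of the other types 9.40 ± 0.46, adjusted p = 9.4e-12), and TRPM1 at 14.6 and 373. PAX3, a transcription factor of the neural crest, was similar in both libraries (93.3 and 118 CPM against 1.09 in Astrocytes).

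Among the epithelial types, Prostate cells held CEACAM5 at 32.5 and 101 CPM against 1.44 in Bladder (10.71 ± 0.39, adjusted p = 5.7e-12), the hair follicle keratin KRT75 at 125 against 7.31, MCF2L2 at 90.2 against 5.09 and the tetraspanin CD151 at 998 ± 829 against 97.5. Bladder cells held FABP4, a fatty acid carrier, at 437 CPM in both libraries against 2.98 in Uterine (10.08 ± 0.26, adjusted p = 3.0e-14), DHRS2 at 469 against 25.9 and PRAC1 at 11.7 against 0.485 (DESeq2 Wald adjusted p = 0.0962). RPL10 was listed at 448 CPM in Bladder and 1.49 in the next type, a value that is uncertain because this ribosomal protein gene has many near-identical copies. Uterine cells held the metallothioneins MT1G (118 against 5.47 CPM) and MT1H (91.5 against 1.78), the defensin DEFB4A (14.7 against 0.237, DESeq2 Wald adjusted p = 0.244) and SPRR2F (24.8 against 0.738). HMEC held the retinol-esterifying enzyme LRAT (148 ± 84.1 against 23.8 CPM), CNTN3 (36.4 against 2.95), PRMT8 (19.7 against 2.82) and QRFPR (17.5 against 0.577). Airway cells held the lipid transporter MFSD2A (58.0 ± 0.99 against 10.6 CPM), LRRC4 (56.8 against 18.02) and the tight junction gene MARVELD2 (10.5 against 2.48; the margin was lost in limma on log2(TPM + 1), with a log2 fold of 1.46). Ovarian cells held the acute phase genes SERPINA3 (110 ± 40.1 against 11.8 CPM) and HP (41.8 against 7.38), OLFM4 (50.6 against 8.95) and the claudin CLDN18 (11.6 against 0.564). Esophageal cells held LMO2 (40.0 against 11.4 CPM), PLSCR4 (29.5 against 10.8) and the BMP antagonist SOSTDC1 (14.02 against 3.43). Colon cells held PDE9A, a phosphodiesterase of cyclic GMP (111 ± 19.0 against 45.1 CPM in Thyroid, adjusted p = 2.3e-06). The n was 2 libraries for each of these values.

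Several of the smaller sets changed in size when single libraries were left out. The filter keeps more genes when a group is left with 1 library, so a rise alone does not show dependence on that library. Pancreas had 3 genes without its replicate 1 and had 144 without its replicate 2, and its CDKN1C, a cell cycle inhibitor, was at 240 CPM in replicate 1 and 11.8 in replicate 2. Without Pancreas replicate 1 the log2 fold of CDKN1C was -0.35 (adjusted p = 0.837), and limma on log2(TPM + 1) and log2(TPM + 0.1) gave adjusted p = 0.126 and 0.146. Leaving out any single library of another type gave 48 to 53 Pancreas genes. Renal had between 11 and 20 genes when any single library was left out, the most (20) without Thyroid replicate 1 and 13 without Renal replicate 2. The count for HMEC rose to 196 without HMEC replicate 2 and 141 without Keratinocytes replicate 1, that for Ovarian to 110 without Ovarian replicate 1, that for Colon to 10 without Colon replicate 2, that for Thyroid to 36 without Thyroid replicate 2 and that for Melanocytes to 570 without Melanocytes replicate 1. Other named genes of these types were not kept throughout. PTGER2 in Colon (16.5 CPM) did not pass the margin without Colon replicate 1 (log2 fold 3.56) or without Melanocytes replicate 2 (3.87), nor did KRT86 in Colon (57.7 CPM) without Colon replicate 1 (4.12), Esophageal replicate 1 (4.42) or Thyroid replicate 1 (4.42). FOXF2 in Esophageal (22.4 CPM) did not without Melanocytes replicate 1 (4.99) or Ovarian replicate 2 (5.00), and RIPPLY3 in Thyroid (30.4 CPM) did not without Pancreas replicate 1 (3.90) or Thyroid replicate 2 (3.89). In limma on log2(TPM + 1) PTGER2 (log2 fold 2.01) and KRT86 (3.24) did not pass it either, nor KRT86 on log2(TPM + 0.1) (4.41). RGCC in Thyroid (38.5 CPM) lost its call without Thyroid replicate 1 (adjusted p = 0.0987) and its margin without HMEC replicate 2 (3.597). PLGRKT in Airway (20.1 CPM) lost its call without either Airway library (adjusted p = 0.0839 and 0.137). The top genes of Renal and Thyroid by margin were readthrough transcripts (ISY1-RAB43 at 66.4 CPM and DNAJC25-GNG10 at 43.3), whose reads cannot be separated from those of the genes they join. ISY1-RAB43 lost its call without Renal replicate 2 (adjusted p = 0.0554) and its margin without Melanocytes replicate 1 (2.03), and DNAJC25-GNG10 its margin without Airway replicate 1 (7.62) and its call in the DESeq2 Wald test (adjusted p = 0.0627).

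Lists of genes known for each cell type then tested whether a culture expressed the genes its label implies. All 26 B cell genes were higher in GM12878 and all 16 melanocyte genes in Melanocytes, and each had its highest mean there. All 30 genes of keratinocyte differentiation were higher in Keratinocytes, 27 of them with their highest mean there. The counts adjusted over the list alone were the same. PTPRC (CD45) was at 393 and 423 CPM in GM12878 (10.44 ± 0.25) and PAX5, the B cell transcription factor, at 224 and 231 (10.30 ± 0.20). KRTDAP was at 1369 and 1709 CPM in Keratinocytes (11.46 ± 0.31) and filaggrin 2 (FLG2) at 139 and 692 (12.75 ± 0.47). SOX10 was at 5.70 and 105 CPM in Melanocytes (9.44 ± 0.46) and the pigment enzyme TYRP1 at 176 and 4219 (9.42 ± 0.39). The list test gave adjusted p = 2.0e-25, 4.5e-24 and 3.9e-22 for these 3 types. In Astrocytes 12 of 16 measured genes were higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 5.4e-07), among them the progenitor factor LHX2 at 253 and 79.4 CPM (9.68 ± 0.24) and the glial filament GFAP at 60.0 and 11.5 (9.05 ± 0.39).

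Epithelial identity genes were expressed to different degrees. Of all genes listed, measured or not, 13 of 21 were under 1 CPM in Airway and 11 of 18 in Colon. In Ovarian 7 of 18 were under 1 CPM, in HMEC 6 of 18, in Bladder 5 of 16 and in Uterine 3 of 17. In Bladder 10 of 13 measured genes were higher (12 adjusted over the list alone, camera adjusted p = 2.7e-11), with uroplakin UPK1B at 230 and 232 CPM (6.35 ± 0.57, adjusted p = 1.7e-07) and UPK3A at 2.94 and 3.10. In Uterine 9 of 15 were higher (12 adjusted over the list alone, adjusted p = 7.6e-07), led by SOX17 at 225 and 207 CPM (5.92 ± 0.42), with PAX8 at 59.4 and 53.8. In Airway 9 of 13 were higher (9 adjusted over the list alone, adjusted p = 6.7e-04), among them TP63, the regulator of basal cells, at 109 and 106 CPM (5.15 ± 0.35), KRT5 at 1570 and 1675, and NKX2-1 at 2.51 and 2.74. In Ovarian 11 of 15 were higher (11 adjusted over the list alone, adjusted p = 1.5e-05), with WT1 at 25.3 and 22.3 CPM (4.62 ± 0.50). In Colon 7 of 10 were higher (8 adjusted over the list alone, adjusted p = 0.0016), with carbonic anhydrase CA2 at 13.2 and 14.6 CPM and EPCAM at 409 and 408. None of the Ovarian or Colon list genes had its highest mean in its own type. WT1 was higher in Esophageal (29.1 CPM), EPCAM in Thyroid (539 CPM) and CDX2, a factor of intestinal identity at 0.608 and 0.198 CPM in Colon, in Ovarian (2.09 CPM). In HMEC 7 of 15 were higher and 1 lower (9 and 1 adjusted over the list alone, adjusted p = 0.0085; adjusted p = 0.218 with an estimated correlation), with the growth factor AREG at 3503 and 5456 CPM (3.37 ± 0.31, adjusted p = 2.8e-07) and KRT14 at 91.8 and 1267. The HMEC call was lost without HMEC replicate 2 (adjusted p = 0.0661).

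The squamous list of Esophageal cells was lower in that culture than in the other types (adjusted p = 2.5e-04; adjusted p = 0.225 with an estimated correlation), with 3 of 14 genes lower and none higher by the gene test (8 lower adjusted over the list alone). KRT6A was at 68.2 and 35.7 CPM (-3.56 ± 0.91, adjusted p = 0.011) and TRIM29 at 2.89 and 1.57 (-3.26 ± 0.72, adjusted p = 0.0040). The Pancreas, Prostate, Renal and Thyroid lists did not pass, at adjusted p = 0.128, 0.0793, 0.284 and 0.251, with 3 of 11, 5 of 15, 1 of 10 and 1 of 8 measured genes higher (5, 4, 1 and 1 adjusted over the list alone). PDX1, a pancreatic transcription factor, was at 0 CPM in Pancreas replicate 1 and 3.42 in replicate 2. HOXB13 was at 9.43 and 3.44 CPM in Prostate (5.38 ± 0.64, adjusted p = 3.3e-06), the aminopeptidase ANPEP at 39.7 and 43.5 in Renal (3.74 ± 0.55, adjusted p = 1.5e-04) and HHEX at 8.73 and 9.33 in Thyroid (2.73 ± 0.56, adjusted p = 0.0021). Of the genes listed for Thyroid 12 were under 1 CPM in that culture, and 16 of those listed for Renal were. Without Pancreas replicate 1 the Pancreas list passed (adjusted p = 0.0011) and so did the Prostate list (adjusted p = 0.0455). With an estimated correlation 9 of the 11 list calls held, all but those of Esophageal and HMEC.

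The 6 CellBiologics types, of one supplier and medium, were compared with the 5 types of other suppliers (Airway, Bladder, HMEC, Prostate and Uterine). No tissue occurred on both sides, so supplier and medium cannot be told apart from tissue of origin. The test counted the 6 types as separate units. Yet Colon, Renal and Thyroid correlated at a mean of 0.977, near their own replicates (lowest 0.985). If some of these cultures were one kind of cell, the adjusted p-values and the number of genes called would be overstated. WT1, a transcription factor of mesothelium and kidney, was at 19.8 ± 5.47 CPM (SD, n = 6 cell types) in the CellBiologics types and at 0.213 ± 0.111 (n = 5) in the others (log2 fold 6.34 ± 0.44, adjusted p = 4.6e-05). ANKRD1, a target of the YAP pathway, was at 1553 ± 648 CPM against 23.3 ± 12.3 (5.88 ± 0.50), the matrix protein MGP at 82.1 ± 41.3 against 1.13 ± 0.78 (6.02 ± 0.53) and the neurotrophin NTF3 at 19.4 ± 12.1 against 0.171 ± 0.063 (6.61 ± 0.61), each with adjusted p = 1.2e-04. The other genes with the largest folds were ALPP, UNC5A, RNF157, GGT5, SERPINA5 and CACNG6, with log2 folds from 5.91 to 6.55. Lower in the CellBiologics types were the antioxidant enzyme GPX2 (0.0768 against 22.02 ± 25.9 CPM, -8.40 ± 0.97, adjusted p = 4.3e-04), the cyclin CCNA1 (0.125 against 24.1, -7.69 ± 0.85), HS3ST2 (0.0745 against 10.2, -7.30 ± 0.83), CALML3 (1.36 against 163, -7.15 ± 1.36), the protease MMP10 (1.42 against 133, -6.72 ± 1.12) and IGF2 (0.507 against 45.8, -6.70 ± 1.28).

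Of 16228 genes 3163 passed, 1519 higher and 1644 lower in the CellBiologics types (48.0% higher). On limma's log2(TPM + 1) scale 1737 were higher and 1090 lower (61.4% higher), and on log2(TPM + 0.1) 1737 and 1147 (60.2%). The count was 811 with replicate 1 of each type alone, 3369 with replicate 2 alone, and 1893, 2051, 1854 and 1875 without Colon, Esophageal, Renal or Thyroid. Pancreas replicate 1, of the pair with the lowest correlation, was left out in a further fit that called 4597 genes. Some of the lower genes rested on few types. FABP4 (-7.13 ± 2.00) was 437 CPM in Bladder and at most 2.98 in the other types, and without Bladder its log2 fold was -0.95 (adjusted p = 0.509). Limma gave adjusted p = 0.283 and 0.257 for FABP4 and 0.341 and 0.325 for RPL10 on the 2 TPM scales. FABP4 also missed the threshold without Colon, Esophageal, Ovarian, Renal, Thyroid or replicate 2 of every type (adjusted p = 0.0516 to 0.0651). RPL10, of uncertain counts as above, likewise stood at 450 CPM in Bladder alone (-0.21, adjusted p = 0.704 without Bladder), and missed it without Colon, Esophageal, Renal, Thyroid or replicate 2 of every type (0.0502 to 0.0557). HOXD11 and the urea transporter SLC14A1 passed in edgeR (adjusted p = 0.014 and 0.016) but not in limma on log2(TPM + 1) (0.154 for both) or log2(TPM + 0.1) (0.167 and 0.153), and IGF2 not in limma on log2(TPM + 1) (0.0647). Calls of single genes hold for this division of the types, and no tissue of origin occurred on both sides of it.

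Genes of basal and squamous epithelium were lower in the CellBiologics types (12 of 20 lower, 14 adjusted over the list alone, camera adjusted p = 2.6e-12; adjusted p = 0.295 with an estimated correlation). The stress-response gene SFN fell by 5.38 ± 0.99 on the log2 scale (adjusted p = 0.0043), S100A2 by 4.36 ± 0.95 (0.0095) and TP63 by 4.32 ± 0.99 (0.012). TP63 was at means of 0.245 to 0.856 CPM in Colon, Esophageal, Ovarian, Renal and Thyroid and at 21.6 to 107 CPM in Airway, Bladder, HMEC, Prostate and Uterine. In Pancreas it was at 19.3 CPM in replicate 1 and 0.91 in replicate 2. Without replicate 2 of every type the calls of S100A2 (adjusted p = 0.0909), TP63 (0.0773) and KRT15 (0.140) were lost. KRT17 also lost its call in 7 of the alternatives that left libraries out (adjusted p = 0.0616 to 0.134). KRT6B, not called (adjusted p = 0.0755), passed without Pancreas replicate 1 (0.0013). The pan-epithelial list did not move as a set (3 higher and 1 lower of 22, the same adjusted over the list alone, adjusted p = 0.860). GRHL2, an epithelial transcription factor, was at 33.8 to 52.9 CPM in Colon, Renal and Thyroid, 1.52 in Esophageal and 2.56 in Ovarian. EPCAM was at 398 to 539 CPM in Colon, Renal and Thyroid, 20.7 in Esophageal and 42.1 in Ovarian. KRT18 was higher by 1.34 ± 0.31 (adjusted p = 0.013; 0.179 without replicate 2 of every type). MARVELD2 was lower (-3.80 ± 0.79), and its call was lost in limma on log2(TPM + 1) (0.0506).

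Lists of cell types other than epithelium were read for cells the cultures could hold. Endothelial genes KDR, a VEGF receptor (5.37 ± 0.66, adjusted p = 6.3e-04), and PECAM1 (5.78 ± 1.21, adjusted p = 0.0080) were higher in the CellBiologics types, 2 of 5 measured genes (2 adjusted over the list alone), without a call for the list (adjusted p = 0.0627). That list passed without Colon, Pancreas, Renal, Thyroid or Uterine (adjusted p = 0.0332, 0.0423, 0.0404, 0.0476 and 0.0241). Of the fibroblast list 3 of 13 measured genes were higher and 3 lower (4 and 4 adjusted over the list alone, adjusted p = 0.992). Its median log2 fold was 0.82 while the test pointed down. The fibroblast proteoglycan LUM was higher (4.84 ± 0.83, adjusted p = 0.0030), as was ZEB1 (3.27 ± 0.94), while FAP (-4.14 ± 1.24), MMP2 (-3.94 ± 1.23) and POSTN (-3.38 ± 0.98) were lower. LUM kept its call in every alternative, while ZEB1, FAP, MMP2 and POSTN each lost it in 6 or more, among them limma on log2(TPM + 1) (adjusted p = 0.122, 0.0823, 0.0505 and 0.0644) and the fit without Esophageal (0.0663, 0.0735, 0.0653 and 0.0642). In smooth muscle 1 of 5 genes was lower (1 adjusted over the list alone, adjusted p = 0.312). Leukocyte genes had 1 higher and 1 lower of 5 (1 and 2 adjusted over the list alone, adjusted p = 0.773). Neuron genes had 2 lower of 5 (2 adjusted over the list alone, adjusted p = 0.0743), and this list passed with log2(TPM + 1) (0.0396), without replicate 1 of every type (0.0130), without Pancreas (0.0322) and without Pancreas replicate 1 (0.0408).

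Because the CellBiologics types resembled each other, their restricted genes were counted again against the types of other suppliers only, a choice made after the values were seen. The counts were then 353 for Colon, 351 for Esophageal, 369 for Ovarian, 209 for Pancreas, 389 for Renal and 458 for Thyroid. Of these, 204, 182, 197, 155, 226 and 226 were counted in at least 4 of the 6 types, which were all set against the same other types, and 41, 58, 56, 30, 27 and 71 in no other of the 6.

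**Figure D3:**
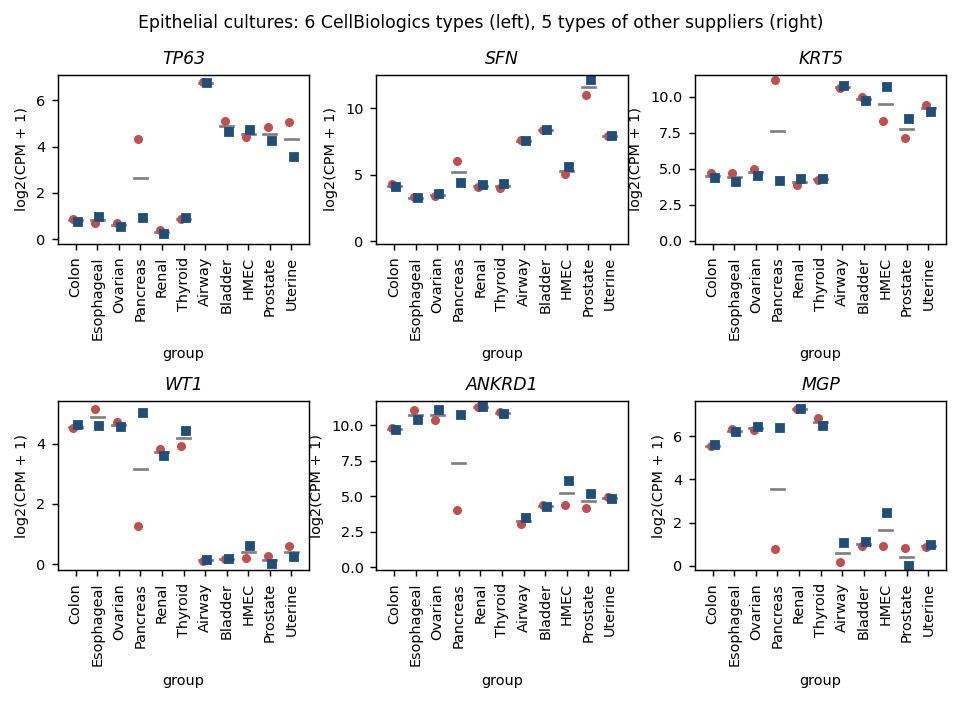
Expression of TP63, SFN, KRT5, WT1, ANKRD1 and MGP in each epithelial type as log2(CPM + 1), with replicate 1 as a circle, replicate 2 as a square and their mean as a line. WT1 was at 12.2 to 29.1 CPM (group means) in the CellBiologics types and at most 0.344 in the others, and the 2 Pancreas libraries differed in TP63 and WT1.

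The melanoma lines were compared with melanocytes, their normal counterpart, to find genes that differ in the tumour lines. The lines had received 1 µM DMSO for 24 h in media with 10% FBS, while the melanocytes were untreated and in another medium, so treatment and medium differ along with cell type. PRAME, a cancer-testis antigen, was at 0.234 CPM in melanocytes and at 1141 in COLO 829, 989 in SK-MEL-5 and 575 in WM-266-4 (log2 folds 12.31 ± 0.28, 12.12 ± 0.28 and 11.29 ± 0.27, with adjusted p = 2.6e-05, 4.2e-05 and 4.9e-05). CSAG1, from the same class, had 0 counts in both melanocyte libraries, which allows up to 0.169 and 0.149 CPM, against 21.7, 24.4 and 34.1 CPM in the lines. The collagen COL19A1 (19.1, 25.1 and 24.8 CPM), the ephrin receptor EPHA3 (25.2, 10.5 and 7.85) and the GABA receptor subunit GABRA3 (9.19, 5.76 and 21.5) also had 0 counts in melanocytes. So did MAGEA6 (41.2, 88.2 and 47.6 CPM, a paralog of MAGEA3), HOXD13, DSCR8, ITIH5 (432 CPM in WM-266-4) and SCARA5 (40.5 CPM in SK-MEL-5), while TAF6 and APOD had 1 count. These 12 genes kept their calls in all 3 lines whichever library was left out. In limma on log2(TPM + 1) ITIH5 lost its call in COLO 829 (adjusted p = 0.143, at 1.81 CPM) and SCARA5 in WM-266-4 (0.0747, at 1.53 CPM).

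Lower in all 3 lines were genes that differed widely between the 2 melanocyte libraries. COL1A1, the main chain of type I collagen, was at 4886 CPM in melanocyte replicate 1 and 31.3 in replicate 2, against 0.161, 0.603 and 0.0646 CPM in the lines (-13.94 ± 2.74, -11.99 ± 2.51 and -15.19 ± 2.91). The BMP antagonist GREM1 was at 703 and 15.0 CPM, the protease PLAU at 37.3 and 2.73, EREG at 91.5 and 2.34 and the noncoding RNA MEG3 at 43.8 and 1.84. KIT, the receptor for stem cell factor, went the other way, at 5.58 and 183 CPM, and had 0 to 7 counts in each line. Leaving out 1 library of a line ended the call in that line for GREM1 (adjusted p = 0.0815 to 0.151), MEG3 (0.128 to 0.151), PLAU (0.104 to 0.124), COL1A1 (0.0695 to 0.0847), EREG (0.0973 to 0.174) and KIT (0.0598 to 0.0938). It ended those of KRT7 in WM-266-4 (0.0833 and 0.0917) and of LGR6 in all 3 lines (0.0502 to 0.0881), with SK-MEL-5 replicate 1 the exception. In limma on log2(TPM + 1) COL1A1 (0.0584 to 0.0606) and EREG (0.0672 to 0.0717) were called in no line, and in the DESeq2 Wald test LGR6 was not called in COLO 829 (0.0507). Libraries of the other lines mattered too for GREM1 (0.0568 to 0.0577 without a WM-266-4 library), EREG (0.0681 to 0.0698), MEG3 (0.0546 to 0.0648) and PLAU (0.0506 and 0.0511 without a COLO 829 library). The epithelial genes KRT5 (16.6 and 12.7 CPM), KRT19 and FGFBP1 were at 0 counts in the lines apart from 1 count of KRT19, and kept their calls. Their level in melanocytes was within 3 times that expected from reads of other libraries, as was that of 95 of all 1294 lower genes.

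Of 18986 genes, 7818 passed in COLO 829 (4100 higher and 3718 lower), 7983 in SK-MEL-5 (4286 and 3697) and 7248 in WM-266-4 (4075 and 3173). All 3 lines shared 2157 higher and 1294 lower genes. Independent lists of these sizes would share 198.7 and 121. Simulated groups without any change shared a mean of 2.55 (highest 10) and 0 over 20 draws. They had a mean of 6 genes (highest 20) called in at least 1 line, against 12098 observed. With so few calls the simulated shared count had to be small. It does not show what lines that each changed would share through common controls. In each draw all 3 groups were set against the same 2 simulated melanocyte libraries. These were drawn from the pooled mean of the real pair with a spread estimated from it, so the real values of that pair did not enter. Part of the excess may come from the shared controls, since 2 melanocyte libraries cannot be divided into sets of 2. Fold changes of COLO 829 and SK-MEL-5 correlated across genes at r = 0.73, those of COLO 829 and WM-266-4 at 0.713 and those of SK-MEL-5 and WM-266-4 at 0.65, below the 0.840 to 0.842 of simulated unchanged groups. The covariances were 6.40, 6.00 and 5.40 against 0.770 and 0.771 simulated. Without melanocyte replicate 1 the counts were 10237, 10039 and 10039 with 2898 higher and 2165 lower in all 3 lines, and without replicate 2 they were 10455, 10756 and 9953 with 2997 and 2594. Of the 2157 and 1294 genes, 1968 and 1067 were called without replicate 1, and 1928 and 1143 without replicate 2. Leaving out a library of the line itself gave 3732 or 3899 genes for COLO 829, 3406 or 3368 for SK-MEL-5 and 3344 or 3437 for WM-266-4. The number shared by all 3 lines was then 1967 or 2026, 1795 or 1778 and 1879 or 1859. The number of lower genes changed more than that of higher ones, with 1354 to 1483 higher and 423 to 543 lower genes then shared.

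The line libraries also stood apart from all 30 other libraries. In 55 genes with a symbol, at 10 CPM or more, the lowest line library was at least 5 times the highest of the 30 others, while no other set of 3 groups had more than 2 such genes. These 55 include BBC3 and the antigens PRAME, MAGEA6 and CSAG1. Of the genes called in all 3 lines, 1074 of the 2157 higher and 241 of the 1294 lower separated the 6 line libraries from every one of the 30 others, which left 1083 and 1053 without them. Whether the lines were prepared or sequenced apart is not stated, and a library batch and the difference between lines and melanocytes cannot be told apart here.

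**Figure D4:**
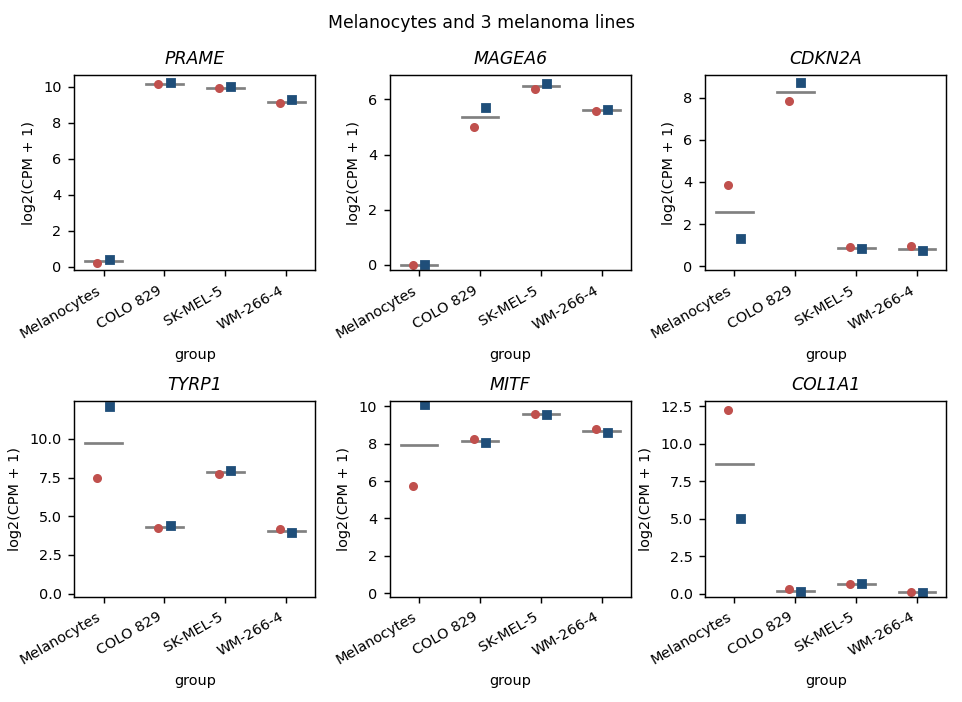
Expression of PRAME, MAGEA6, CDKN2A, TYRP1, MITF and COL1A1 in melanocytes and the melanoma lines as log2(CPM + 1), with replicate 1 as a circle, replicate 2 as a square and their mean as a line. PRAME was at 575 to 1141 CPM (means) in the lines and 0.234 in melanocytes, and COL1A1, TYRP1 and MITF differed between the melanocyte libraries.

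Of the 14 gene lists tested over the mean of the 3 lines, the cancer-testis antigens passed (adjusted p = 3.8e-06; adjusted p = 0.0787 with an estimated correlation). Among 12 measured members 8, 10 and 9 were higher in COLO 829, SK-MEL-5 and WM-266-4, 7 of them in all 3, and 1 was lower in COLO 829. For each list below, the counts per line are in that order, and counts adjusted over the list alone differed from them by at most 2 genes. The pigmentation list was split, with 0, 1 and 0 of 14 genes higher and 6, 0 and 3 lower (adjusted p = 0.483). TYRP1 was lower in the mean of the lines (-5.60 ± 0.82, adjusted p = 0.0025) at 18.8, 228 and 15.4 CPM. Its level, given above, was far higher in melanocyte replicate 2 than in replicate 1. GPR143, the melanosome receptor, was also lower in the mean of the lines (-4.56 ± 0.38) at 0.0981, 38.0 and 9.24 CPM. Without melanocyte replicate 1 this list passed as lower (adjusted p = 8.9e-04), and without replicate 2 it pointed up (0.0941). SOX10 was at 84.8, 95.0 and 106 CPM in the lines against 5.70 and 105 in the 2 melanocyte libraries, and MITF, the regulator of pigment genes, at 283, 766 and 410 CPM against 52.2 and 1085. Melanocyte transcription factors had 2, 1 and 2 of 9 higher and 2, 1 and 3 lower (adjusted p = 0.963), with PAX3 lower in the mean of the lines (-2.62 ± 0.19, adjusted p = 2.5e-04) at 24.2, 14.8 and 11.9 CPM.

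MAPK pathway output genes had 7, 5 and 9 of 15 higher and 2, 2 and 1 lower (adjusted p = 0.302). The feedback phosphatase DUSP4 was higher in the mean of the lines (1.83 ± 0.23, adjusted p = 0.0013) at 644, 309 and 592 CPM against 112 and 184 in melanocytes, as were SPRY4 (2.52 ± 0.30) and ETV4 (2.40 ± 0.46). Genes of the dedifferentiated state had 1, 0 and 2 of 15 higher and 7, 6 and 1 lower (adjusted p = 0.302). EGFR was at 40.5 and 4.67 CPM in melanocytes and 0.0378, 3.99 and 0.0134 in the lines. This list passed as lower without melanocyte replicate 2 (adjusted p = 0.0026). The fibroblast list, which holds cells the melanocyte culture could contain, had 2, 1 and 1 of 19 higher and 9, 11 and 4 lower. In melanocyte replicate 1, 15 of its 22 listed genes were at least 4-fold higher than in replicate 2. The pan-epithelial list had 12, 15 and 12 of 17 lower and the basal list 15, 16 and 16 of 19, but 13 of the 22 pan-epithelial and 14 of the 20 basal genes listed lay, in melanocytes, within 3 times the level expected from reads of other libraries. Smooth muscle had 3, 4 and 2 of 8 lower, endothelium 3, 3 and 2 of 8, leukocytes 3, 4 and 2 of 7 and neurons 3, 2 and 1 of 7, and each of these 4 lists had 3 or fewer higher genes per line.

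Interferon response genes had 3, 2 and 14 of 15 higher and 1, 3 and 0 lower (adjusted p = 0.0574). IFIT1 was at 3.30 CPM in COLO 829, 2.47 in SK-MEL-5 and 354 ± 204 in WM-266-4, against 2.09 and 2.78 in melanocytes (mean of the lines 2.63 ± 0.39, adjusted p = 0.0025), and OAS2 at 0.522, 0.558 and 142 ± 80.1 CPM (2.63 ± 0.54, adjusted p = 0.0087). The interferon list passed without melanocyte replicate 1 (adjusted p = 0.0299), without WM-266-4 replicate 1 (0.0210) or 2 (0.0024), and on log2(TPM + 1) (0.0334). Of 12 p53 targets 6, 4 and 6 were higher and 1, 1 and 0 lower (adjusted p = 0.117; 0.01003 without melanocyte replicate 1). BBC3 (PUMA), an inducer of apoptosis, was at 3.95 and 5.32 CPM in melanocytes and 123, 88.2 and 101 in the lines (4.56 ± 0.32, adjusted p = 2.1e-04). Cell cycle inhibitors and tumour suppressors had 3, 0 and 0 of 10 higher and 3, 8 and 4 lower (adjusted p = 0.0574; 0.0080 without melanocyte replicate 2). CDKN1B fell by 1.83 ± 0.29 on the log2 scale in the mean of the lines (adjusted p = 0.0032).

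Glycolysis genes had 10, 4 and 5 of 18 higher and 0, 4 and 2 lower (adjusted p = 0.302; 0.0299 without melanocyte replicate 1). Aldolase ALDOA was at 38.0 and 29.4 CPM in melanocytes and 407, 213 and 253 in the lines (3.12 ± 0.22, adjusted p = 2.2e-04), and hexokinase HK2 was higher by 2.38 ± 0.29. Mitochondrial respiration genes had 4, 10 and 5 of 18 higher and 0, 0 and 1 lower (adjusted p = 0.203; 0.0429 without melanocyte replicate 2). Cholesterol synthesis genes had 1, 1 and 1 of 16 higher and 2, 5 and 5 lower (adjusted p = 0.302; 0.0429 without melanocyte replicate 2), with LSS lower by -1.21 ± 0.23 (adjusted p = 0.0064). Adhesion and matrix genes had 7, 2 and 7 of 17 higher and 6, 12 and 4 lower (adjusted p = 0.481). Tenascin TNC was higher (5.19 ± 0.76, adjusted p = 0.0025) at 50.9, 19.6 and 140 CPM against 2.48 and 0.447, and E-cadherin CDH1 lower (-9.12 ± 0.81, adjusted p = 4.5e-04) at 0.0378, 0.544 and 0.0768 CPM against 12.2 and 136. Proliferation genes had 4, 4 and 2 of 22 higher and 6, 5 and 6 lower (adjusted p = 0.302), with the mitotic kinase AURKB higher at 166, 138 and 99.9 CPM against 23.7 and 26.7 (2.47 ± 0.20, adjusted p = 3.2e-04). Antigen presentation genes had 0, 1 and 2 of 14 higher and 4 lower in each line (adjusted p = 0.349), with the proteasome subunit PSMB10 lower by -1.20 ± 0.13 (adjusted p = 8.7e-04).

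The lines were also tested against each other. CDKN2A, the locus of the inhibitors p16 and ARF, was at 225 and 413 CPM in COLO 829, 0.830 in SK-MEL-5 and 0.786 in WM-266-4, and at 13.3 and 1.44 in the melanocyte libraries (8.57 ± 1.21 and 8.68 ± 1.22 over the other lines, adjusted p = 0.0050 and 0.0053). Its neighbour CDKN2B was at 62.9, 0.274 and 0.206 CPM (7.82 ± 0.98 and 8.26 ± 1.01), and TMSB4X, which binds actin, at 1327, 3.88 and 5.80 (8.41 ± 1.06 and 7.86 ± 1.03). The antigen CTAG2 was at 79.1, 0.123 and 0.0780 CPM. SK-MEL-5 was higher in RASD1 (72.3 ± 32.0 CPM against 0.154 and 0.127), MATK (16.7 CPM, with 1 and 2 counts in the other lines), the ephrin receptor EPHA7 (14.1 CPM against 0.0579, with 3 counts in WM-266-4) and GALNT14 (11.8 CPM). WM-266-4 was higher in the retinaldehyde dehydrogenase ALDH1A3 (417 ± 101 CPM against 1.13 and 1.13, adjusted p = 0.0012 and 9.7e-04), HOXA10 (52.8 against 0.132 and 0.137), the interferon lambda receptor IFNLR1 (20.1 against 0.0201 and 0.0458) and PRRX1 (151 against 0.429 and 0.419).

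COLO 829 differed from SK-MEL-5 in 4249 genes (1942 higher, 2307 lower) and from WM-266-4 in 4151 (1762 and 2389), and SK-MEL-5 from WM-266-4 in 5253 (2539 and 2714). COLO 829 had 626 genes higher than both other lines, SK-MEL-5 1194 and WM-266-4 1273. The spread of the melanocyte libraries enters these tests, and without melanocyte replicate 1 the 3 counts were 8913, 8835 and 9843, and without replicate 2 they were 8946, 8901 and 9855. Leaving out a COLO 829 library gave 1203 or 1286 and 1079 or 1056 for the first and second comparison, leaving out an SK-MEL-5 library gave 1166 or 1131, 2220 or 2228 and 1495 or 1501 for the 3, and leaving out a WM-266-4 library gave 2720 or 2734, 1134 or 1413 and 1847 or 1936. The CDKN2A call was lost without either SK-MEL-5 library (adjusted p = 0.0584 and 0.0614) or either WM-266-4 library (0.0596 and 0.0597), and that of CTAG2 against WM-266-4 without either WM-266-4 library (0.0536 and 0.0541). MATK lost a call without either COLO 829 library (0.0619 and 0.0581) or WM-266-4 replicate 2 (0.0508), GALNT14 without any library of the pair compared (0.0656 to 0.125) and against COLO 829 in limma on log2(TPM + 1) (0.0502), and PRRX1 without any library of the lines (0.0704 to 0.218).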

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

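Of the tests in this part, only the comparison with low expression by the cultured cells themselves was fixed before its result was seen, and all others were chosen after the pattern was seen.

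The CellBiologics cultures were alike across tissue labels, apart from Pancreas replicate 1 (mean r 0.882 with Colon, Renal and Thyroid). If the 11 types are taken as separate units, chance does not account for their division from the other epithelial types. Only 1 of 100 splits of the 11 types (the real one, of 462 possible) called as many genes as the real 3163, and the highest other called 56. The likeness of Colon, Renal and Thyroid leaves open whether they are separate units. The background of B cell and melanocyte genes in Thyroid was 0.09518 of that in Colon and Renal. For these genes that argues against reads of other libraries as the source of the likeness. Keratinocyte genes went the other way, at 4.733% and 4.739% of the mean over the pool of libraries in Thyroid. They were at 1.823% and 1.38% in Colon and 1.318% and 1.599% in Renal. Whether the cultures expressed these genes themselves was not tested, so such reads are not excluded. One kind of cell under several tissue labels stays open, as 0 HOX genes differed 4-fold in any pair of Colon, Renal and Thyroid, but at most 1 did in pairs with Esophageal and Ovarian, which had far less EPCAM, so the HOX genes do not decide it. One shared medium is undecided, since Esophageal and Ovarian in that medium lay 0.02228 lower in mean r with the 3 types than these did with each other, further than the 0.01 it was set to allow, but at 0.955 above the 0.874 of types from other suppliers, and so is tissue of origin, which the labels give and which was not tested apart from supplier and medium.

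Melanocytes replicate 1 was low in pigment genes and high in collagen genes. Reads of other libraries do not account for the fibroblast list genes at 10 CPM or more there (15 of 22, collagen genes among them), which lay at a median of 544.9 times the level predicted from the pool. Fibroblast-type cells or RNA in the sample could raise 15 of 22 fibroblast genes at least 4-fold, but would dilute all melanocyte genes alike, and 13 of 16 lay within 2-fold of the median ratio of 4.88%, with PAX3 at 78.86%. The same cells in a state with less pigment would keep their transcription factors, and 1 of 4 (PAX3) stayed within 4-fold, with SOX10 at 5.429%, MITF at 4.814% and TFAP2A at 13.43% of replicate 2. Fibroblast-type cells and a state with less pigment cannot be told apart from these values, and no biological explanation in the labels separates the 2 libraries.

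The melanoma line libraries stood apart from the 30 other libraries. In the 2 Melanocytes and 2 GM12878 libraries, low levels of genes of other cell types are consistent with reads of other libraries in one pool, as 2 unrelated gene lists lay at most 1.682 times apart as fractions of the pool mean. Other libraries differed, with B cell genes at 0 and melanocyte genes at 17.56% of it in Keratinocytes replicate 2, and keratinocyte genes at 0 and B cell genes at 0.02115% to 0.1462% in the 6 line libraries. The level of 26 B cell genes in 20 other libraries followed that in GM12878 (Spearman correlation 0.8038). In those libraries this argues against low expression by the cultured cells themselves. Airway, Thyroid, Keratinocytes and Melanocytes were left out of that correlation, so it does not cover them. B cell genes were at 0.3807% of the pool mean or less in the Airway, Thyroid and Keratinocytes libraries, lower than in any of the 20 used. A library or processing batch remains possible, as 20 genes at 1 CPM or more in every other group were 5-fold higher in each line library than in each of the 30 others, against at most 1 in any other of the 816 sets of 3 groups, but the lines are also the only melanomas, had DMSO and grew in media of their own, so this batch and the difference between lines and melanocytes cannot be told apart.

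Among 40 groups of cell types searched for a type far from the others with Dixon's criterion, 11 stood out, in 9 genes. It picks about 1 in 20 groups by chance, but these genes had been named for large supplier folds, which a single extreme type can produce, so that rate does not hold for them. Bladder lay far above the other types outside CellBiologics in FABP4 (436.8 CPM, nearest 2.977), RPL10 (449.9, nearest 1.415), IGF2 (177, nearest 38.7) and SLC14A1 (120.9, nearest 34.83). HMEC lay above them in MGP (2.476 CPM, nearest 1.007) and SERPINA5 (0.4894, nearest 0.1551). Among the CellBiologics types, Ovarian stood out in SERPINA5 (31.79 CPM, nearest 12.25) and GPX2 (0.1363, nearest 0.07836). Pancreas did in MMP10 (5.647, nearest 0.7725) and CALML3 (4.045, nearest 1.437) and Thyroid, on the low side, in IGF2 (0.2015, nearest 0.5087). Some of these levels rest on few counts. All CellBiologics types together had 21 counts of GPX2 and 144 of IGF2, and the types of other suppliers 28 of SERPINA5. Counting error may set a type apart at such levels.

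Among 36 differences between lines tested by edgeR in genes named for a line, 12 in 6 genes went with opposite calls of the lines against melanocytes. These genes had been named because edgeR called them higher in their line than in both others. The differences of that line were thus called in advance, and the 12 are a description, not a test. CDKN2A was higher in COLO 829 by a log2 fold of 8.565 against SK-MEL-5 and 8.684 against WM-266-4, and CDKN2B by 7.82 and 8.263. MATK differed by -10.15 for COLO 829 against SK-MEL-5 and 9.201 for SK-MEL-5 against WM-266-4. Against WM-266-4, IFNLR1 was at -9.553 in COLO 829 and -8.643 in SK-MEL-5, HOXA10 at -8.532 and -8.523, and ALDH1A3 at -8.497 and -8.489.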

How the results depend on the processing

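The comparison with types of other suppliers only, the fit without Pancreas replicate 1 and the counts without genes apart or at background were chosen after the data were seen, and all other alternatives before. In simulated counts the tests missed most 2-fold changes, and the depth of Prostate replicate 2 (2.62 M) means that a count of 0 there allows up to 1.14 CPM.

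Without the filter on low counts, more genes were tested and the counts of restricted genes were 87 for Airway, 1214 for Astrocytes, 159 for Bladder, 15 for Colon, 76 for Esophageal, 165 for HMEC, 107 for Ovarian, 85 for Pancreas, 23 for Renal, 54 for Thyroid, 1914 for GM12878 and 603 for Melanocytes. The DESeq2 Wald test gave 35 for Airway, 59 for Bladder, 18 for Esophageal and 5 for Renal. Limma on log2(TPM + 1) gave 29 for Airway, 472 for Astrocytes, 2 for Colon, 16 for Esophageal, 44 for HMEC, 32 for Ovarian, 3 for Pancreas, 862 for Prostate, 4 for Renal, 7 for Thyroid, 60 for Uterine, 670 for GM12878, 590 for Keratinocytes and 184 for Melanocytes, and on log2(TPM + 0.1) it gave 2 for Pancreas and 228 for Melanocytes. Against types of other suppliers only, the counts were 353 for Colon, 351 for Esophageal, 369 for Ovarian, 209 for Pancreas, 389 for Renal and 458 for Thyroid, since fewer types had to be exceeded. Without the genes that set the lines apart from all 30 other libraries 2136 genes were called in all 3 lines, and without those at the background level 3356. Of the melanoma gene lists 0 passed with an estimated correlation and 2 on log2(TPM + 1). Without replicate 2 of every type the supplier count was 811, and without replicate 1 of every type 3369. Apart from these constructions the cause was not tested.

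With 1 library left out, the counts ranged from 4 to 10 for Colon, 93 to 196 for HMEC, 51 to 110 for Ovarian, 3 to 144 for Pancreas, 11 to 20 for Renal, 23 to 36 for Thyroid and 319 to 570 for Melanocytes. Against melanocytes they were 3732 to 10455 for COLO 829, 3368 to 10756 for SK-MEL-5, 3344 to 10039 for WM-266-4 and 1778 to 5591 for all 3. Between lines they were 1131 to 8946 for COLO 829 and SK-MEL-5, 1056 to 8901 for COLO 829 and WM-266-4 and 1495 to 9855 for SK-MEL-5 and WM-266-4. The supplier count ranged from 1854 without Renal to 4263 with a type left out, and the number of melanoma gene lists called from 1 to 5. The filter keeps more genes when a group is left with 1 library, and without a Melanocytes library the shared spread no longer holds that pair. All other counts stayed within 1.5 times. CDKN1C ranged from -0.3452 without Pancreas replicate 1 to 4.107 without replicate 2. Without Melanocytes replicate 1 and without replicate 2, values over the mean of the lines were -4.24 and 0.2385 for TRPM1, -4.096 and 0.3438 for MLANA, -2.293 and 0.8483 for RAB27A, -2.442 and 0.2533 for TFAP2A, 0.3598 and -3.124 for IRF1 and 1.692 and -2.23 for CDKN1A, from the difference of that pair.

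Over all alternatives and apart from the values above that turned, named restricted genes kept their call 1896 times and lost it 27 times. Melanoma genes stayed on their side of the threshold 2366 times, lost the call 224 times and gained it 26 times, and supplier genes 947, 104 and 12 times. For restricted genes most of these outcomes came from leaving out 1 library, usually of a cell type other than the gene's own. The totals therefore do not measure how far a call rests on the libraries of its own type. For melanoma and supplier genes the first number includes genes uncalled in both fits. Uncalled values could change sign, as RAB27A did on log2(TPM + 1) (0.2276) and log2(TPM + 0.1) (0.2451). Gene lists kept their side, lost the call and gained it 505, 3 and 2 times by identity, 156, 1 and 11 times in melanoma and 109, 1 and 9 times by supplier.

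Same-numbered replicates share only a number, as 6 of 153 pairs of groups had correlated deviations over 0.1 and 11 under -0.1 (median -0.004994). The replicate block moved no count by over 1.5 times, with 7256, 7349 and 6659 genes for COLO 829, SK-MEL-5 and WM-266-4 and 11 identity lists.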

Other observations

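All values in this part were chosen after the data were seen and were not tested.

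The Pancreas libraries differed in several epithelial genes. Replicate 1 carried TP63, of basal cells, at 19.3 CPM and the genes of basal and squamous epithelium at a median of 502 CPM, against 0.910 and 18.4 in replicate 2. Replicate 2 carried EPCAM at 422 CPM, WT1 at 31.6 and PAX8 at 7.93, against 15.1, 1.41 and 0.273 in replicate 1, and the pan-epithelial list at a median of 157 against 52.2 CPM. GRHL2 was alike in both (31.2 and 36.4 CPM). In EPCAM, WT1 and GRHL2 replicate 2 lay near Colon (408, 22.7 and 33.8 CPM).

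Among the genes that set the line libraries apart from all 30 others, CHCHD2, a mitochondrial protein, was at 2028 CPM or more in each line library and at most 382 in any other, RAB5C, of early endosomes, at 667 or more against 77.6, GANAB, a glucosidase of the endoplasmic reticulum, at 472 or more against 32.0, and the kinases AKT2 at 267 or more against 21.9 and PRKACA at 195 or more against 26.8.

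Astrocytes differed between libraries in glial genes, with GFAP at 60.0 and 11.5 CPM and LHX2 at 253 and 79.4. PAX8, of the kidney, thyroid and Müllerian tract, was highest in Uterine (56.6 CPM) and Ovarian (13.2), and lower in Keratinocytes (10.8), Renal (6.61) and Thyroid (5.87). CDX2 was at 0.403 CPM in Colon and 2.09 in Ovarian.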
